A study of Mus musculus with 4 samples.

How the data were processed

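Accessible chromatin was measured by single-nucleus ATAC-seq (10x Genomics Multiome, which assays accessibility and RNA in the same nuclei) in 4 libraries of mouse embryonic stem cells: wild type and Cdc14a/Cdc14b double knockout, each at day 0 and at day 5 of neural differentiation, with 1 library per group. Per the labels, all libraries carry the same clone number, and whether it marks the same derivation in both genotypes is unclear. Each genotype appears with a single clone number, so a difference between cell lines cannot be separated from an effect of the knockout. Per the labels' protocols, the stem cells were grown with feeder cells, which were removed before differentiation and nuclear isolation.

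The authors deposited 1 peak list per library, with 3 columns that give the chromosome, start and end of each peak and no score, height or count. Per the file headers, peaks were called per library by cellranger-arc 2.0.0 on the mm10 reference 2020-A. The submitters' processing notes name Cell Ranger ARC 2.0.0, Scanpy 1.7.2 and mm10. The RNA side of the assay and the cell-by-cell data were not used here. The labels, processing notes and file headers do not say whether doublets were removed before the peaks were called, and no doublet caller was run. Because no count or signal was used, depth per library is unknown, and the number of peaks and covered bp stand in for it. Peaks were of nearly uniform size, with median widths of 873, 877, 879 and 882 bp (wild type and knockout at day 0, then wild type and knockout at day 5). A longer list can come from deeper sequencing, more nuclei or more open chromatin. Peaks on unplaced contigs made up 0.0307, 0.0265, 0.0290 and 0.0272% of the lists.

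Gene positions were taken from a table of the GRCm38.p6 assembly, whose chromosome coordinates are those of mm10. The 21883 protein-coding genes on the assembled chromosomes were used. The table gives the outermost ends of each gene without strand, transcript starts or exons. For each gene the more accessible end was therefore used: the end with more covered bp within 1 kb, summed over the 4 libraries, with ties given to the low-coordinate end. This picked the low-coordinate end in 13108 genes and the high-coordinate end in 8775. This choice was meant to find the promoter but can pick the 3' end, and how often it does was not tested, so a peak at a gene end is not always a promoter peak. In 9456 genes both ends had covered bases, and in 4277 neither had.

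A peak counted as shared when at least 1 bp of it overlapped a peak of the other library. Shares carry 95% exact (Clopper-Pearson) intervals, which cover counting error only. A gene had an end peak when any covered base lay within 1 kb of its end. Locus accessibility was the covered bp in the 50 kb on each side of the gene end, compared as log2 of the ratio of both libraries after adding a pseudocount of 500 bp to each. From each ratio the median over the 20731 genes with any covered base was subtracted; these medians were 0.10 (knockout against wild type, day 0), 0.30 (knockout against wild type, day 5), −0.23 (day 5 against day 0, wild type) and −0.03 (day 5 against day 0, knockout). The median of each of 20 gene lists was placed among 10000 random lists of the same size matched on mean covered bp in deciles, and lists below percentile 2.5 or above 97.5 are called outside the random range. This describes the 4 libraries and is no test of the conditions. Peak regions were also joined across libraries wherever peaks overlapped.

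Before the data were examined, the comparisons, windows, pseudocount, gene lists, the rule for named genes and most alternatives were fixed. The rule names Cdc14a and Cdc14b, 12 genes of pluripotency and early differentiation, the highest and lowest member of each list with at least 2000 bp covered on average, up to 10 list members with an end peak in 1 library only, the 5 highest and 5 lowest genes genome-wide with at least 5000 bp (1 gene per 100 kb), and the 3 widest regions listed in a single library. Members of a list named beyond this rule were chosen after their values were seen, as were the Y-linked genes. The plan called for windows at annotated transcript starts, for exon and intron shares and for sequence motifs. Transcript starts, exons and a genome sequence were not used here, so gene ends replaced transcript starts, and the motif analysis was not run. A planned test with the outermost 5' end needs the strand of each gene, so it was not run. Genes of repeated families, such as Zscan4, Tcstv1, Duxf3, Rhox12 and Vmn2r2, can lose or share reads between copies, and their values are uncertain.

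Alternatives were a reciprocal overlap of 50%, the widest peaks in equal numbers (189571 per library), autosomes only, gene end windows of 500 bp or the end base, at least 250 bp covered, locus windows of 10 kb or the whole gene with 50 kb on each side, numbers of peaks in place of bp, pseudocounts of 100 and 2000 bp, and a minimum mean of 2000 bp. Alternatives added after the data were seen were a peak at either gene end, random lists matched on covered bp and gene density within 1 Mb (in quintiles of each, where the main setting uses deciles of covered bp), and at most 1 list member per 100 kb.

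The overlap step was tested on simulated data by removing 5000 peaks from the wild-type day 0 list, of which 5000 were found, and against bedtools 2.31.1, which gave the same counts. Covered bp equalled a base-by-base count in 300 windows. In the day 0 genotype comparison, 99.5% of simulated lists of 10 genes shifted by 0.4 (log2) fell outside the random range, and 52% of those shifted by 0.2. Without a shift, a first run of 200 simulated lists of 20 genes put 9.5% outside, above the nominal rate. The unshifted case was therefore run again with 2000 lists, of which 5.55% fell outside for 20 genes and 4.2% for 10. These lists were scattered over the genome, so clustered families are not covered. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.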

Results

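The 4 libraries came from mouse embryonic stem cells, which were either wild type or carried a knockout of both Cdc14a and Cdc14b, the genes of a pair of phosphatases that counter cyclin-dependent kinases. Each genotype was sampled at day 0, in medium with the cytokine LIF that keeps the cells pluripotent, and at day 5 of neural differentiation. Nuclei were assayed for chromatin accessibility by single-nucleus ATAC-seq, in which a transposase cuts open DNA, and the values used here are the positions of the accessible regions (peaks) called in each library. Each group held 1 library, so no difference below has a replicate check, and all of them describe these 4 libraries. The lists held 198860 peaks in wild type at day 0, 222257 in the knockout at day 0, 189571 in wild type at day 5 and 227878 in the knockout at day 5. They covered 168.8, 190.3, 162.5 and 197.3 Mb of the mm10 genome. The peaks carried no height and the read depth is unknown, so a missing peak can reflect fewer reads as well as closed chromatin. Values at gene loci are therefore given relative to the median locus of the same comparison.

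Most peaks lay away from the ends of protein-coding genes. Within 1 kb of a gene end lay 12.1% of the peaks of wild type at day 0 (95% exact binomial interval, 12.0 to 12.3), 11.1% in the knockout at day 0 (11.0 to 11.2), 11.3% in wild type at day 5 (11.1 to 11.4) and 10.5% in the knockout at day 5 (10.3 to 10.6). Other gene bodies held 45.2, 45.3, 44.4 and 44.6% of the peaks in the same order, and intergenic sequence held 42.7, 43.6, 44.4 and 44.9%. The intervals cover counting error only.

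At Cdc14a (chromosome 3, 116272553 to 116428741), 18 peaks overlapped the gene in wild type at day 0, 30 in the knockout at day 0, 15 in wild type at day 5 and 26 in the knockout at day 5. Cdc14b (chromosome 13, 64192545 to 64274988) held 9, 14, 12 and 13 peaks in that order. In the 100 kb around the more accessible end of each gene, the knockout had a higher ratio than the median locus at day 0 (0.36 for Cdc14a and 0.47 for Cdc14b, log2) and at day 5 (0.66 and 0.61). A peak only marks accessible DNA, and the labels do not place the deleted sequence, so these values do not check the genotype. In the windows at the gene ends, peaks covered 0, 505, 0 and 502 bp at the low-coordinate end of Cdc14a and none at its other end. The Cdc14a end was thus picked by knockout peaks alone, which can favour a higher knockout ratio in the 100 kb around it. At Cdc14b, peaks covered 0, 945, 511 and 843 bp at the low-coordinate end and 1137, 1141, 888 and 1086 bp at the high-coordinate end, in the same order of libraries.

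Genes of the Y chromosome separated 1 library from the others. The wild-type day 5 library had peaks at the ends of Eif2s3y (1009988 to 1010902), Uty (1245268 to 1246155) and Ddx3y (1286167 to 1286958), all on Y and active in many male cell types. No such peak was listed in wild type at day 0 or in the knockout at either day. Of 10 genes examined in this part of Y, which were chosen after the values were seen, 3 had an end peak in wild type at day 5 and 0 in each of the other libraries. The X chromosome held 4273 peaks in wild type at day 0, 5565 in the knockout at day 0, 4112 in wild type at day 5 and 6659 in the knockout at day 5. Its share relative to the autosomes was higher in the knockout by 0.23 (log2) at day 0 and 0.44 at day 5.

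Knockout and wild-type stem cells at day 0 were compared to ask how the loss of both phosphatases alters accessibility before differentiation. Loci of the core pluripotency factors covered slightly more bp in the knockout than the median locus, led by Dppa4 (0.42) and Dppa2 (0.40), neighbours that share most of their window and encode chromatin regulators of early development. Loci of neural progenitor genes covered less, with Fabp7, a fatty acid binding protein of radial glia, at −0.46 and the eye and forebrain regulator Pax6 at −0.33. Endoderm and fibroblast marker loci covered more bp in the knockout, including Sox7 (0.79), an endoderm transcription factor, and Postn (0.88), a matrix protein of fibroblasts. All of these are log2 ratios of covered bp, 1 library against 1.

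Among the core pluripotency genes, 7 of 10 loci lay above the median locus, with a list median of 0.11 at percentile 98.4 of 10000 random gene lists matched on covered bp. Pou5f1, which encodes the pluripotency factor OCT4, had a ratio of −0.02, Sox2 of 0.20, Nanog of −0.17 and Utf1 of 0.15. In the naive pluripotency list the median was 0.05 (percentile 81.8), and values included Klf4 at 0.61, Esrrb at 0.08 and Zfp42 at −0.46. Formative genes, which mark cells leaving the naive state, had a median of −0.14 (percentile 1.53) with 7 of 10 loci below the median locus. There Fgf5 stood at 0.35 and Otx2 at −0.07. For neural progenitor genes the median was −0.13 (percentile 0.28), 14 of 20 loci lay below the median locus, and Sox1 and Nes had ratios of −0.08 and 0.07.

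Endoderm loci had a median of 0.28 (percentile 99.5) and fibroblast marker loci one of 0.29 (percentile 99.9), with 9 of 12 and 13 of 16 loci above the median locus. The cultures were grown with feeder cells that were removed before the assay, per the labels' protocols. Over the whole spans of the Hox clusters, which hold developmental patterning genes, peaks covered 25.9 kb in wild type and 23.3 kb in the knockout at Hoxa, 40.9 and 38.9 kb at Hoxb, 28.4 and 30.9 kb at Hoxc, and 20.8 and 21.1 kb at Hoxd. The Hox gene list had a median of −0.14 (percentile 0), but neighbouring Hox genes share their windows, so this percentile is more extreme than that of independent loci.

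The other 14 lists had medians inside the central 95% of random lists. They were 0.05 for naive pluripotency, −0.03 for neuron, −0.10 for glia, 0.06 for mesoderm, 0.13 for trophoblast, 0.09 for epidermal and neural crest, 0.18 for blood and endothelium, −0.27 for 2-cell-like, 0.03 for germ line, −0.02 for bivalent, 0.09 for imprinted, 0.08 for mitosis, 0.03 for Polycomb and Trithorax and 0.04 for housekeeping genes.

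Among list members with at least 2000 bp covered on average, locus ratios ran from −0.17 (Nanog) to 0.42 (Dppa4) among core pluripotency genes, from −0.46 (Zfp42) to 0.72 (Nr0b1) among naive genes and from −0.26 (Dnmt3b) to 0.35 (Fgf5) among formative genes. Neural values ran from −0.46 (Fabp7) to 0.33 (Emx2) for progenitor genes, from −0.43 (Neurog2) to 0.56 (Ncam1) for neuronal genes and from −0.36 (Aqp4) to 0.34 (S100b) for glial genes. The germ layer lists ran from −0.35 (Gsc) to 0.44 (Evx1) for mesoderm, from −0.68 (Sox17) to 0.79 (Sox7) for endoderm, from −0.13 (Krt18) to 0.36 (Foxd3) for epidermis and neural crest and from −0.09 (Gata1) to 1.69 (Runx1) for blood and endothelium. Trophoblast genes ran from −0.61 (Elf5) to 0.21 (Tfap2c), germ line genes from −0.61 (Dazl) to 1.18 (Taf7l), 2-cell-like genes from −0.32 (Zfp352) to −0.22 (Duxf3) and fibroblast markers from −0.29 (Twist1) to 0.88 (Postn). Bivalent regulators ran from −0.68 (Sox17) to 0.46 (En1), Hox genes from −0.32 (Hoxb1) to 0.36 (Hoxd13) and imprinted genes from −0.09 (Mest) to 0.51 (Grb10). Mitotic genes ran from −0.27 (Ccna2) to 0.38 (Kif11), Polycomb and Trithorax genes from −0.40 (Kdm6a) to 0.19 (Jarid2) and housekeeping genes from −0.18 (Gusb) to 0.43 (Pgk1). Of the genes named here, Nr0b1, Taf7l and Pgk1, highest in their lists, and Gata1 and Kdm6a, lowest in theirs, lie on X. The share of X peaks was higher in the knockout.

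Of the list members with an end peak in 1 library only, up to 10 with the largest difference are named for each comparison. Ends were picked by coverage without strand, so some can be 3' ends and not promoters. The marked end was the low-coordinate one for Hoxa7 and Gata4 and the high-coordinate one for Dnmt3a, and which end holds the promoter was not checked. Gene ends with a peak in the day 0 knockout and none in wild type included those of Col3a1, Hnf4a, Hoxa7, Hoxb5, Lhx1, Runx1, Sox7 and Trp63. The converse held for genes including Dnmt3a and Hoxa11. Across all 21883 protein-coding genes, 561 had an end peak in the knockout and not in wild type, and 331 the converse. The highest locus ratios genome-wide, among loci with at least 5000 bp covered on average, were those of Ccdc192 (1.93), Runx1 (1.69), Jcad (1.64), Car5b (1.56) and Gm815 (1.55), and the lowest were those of Gm9507 (−1.73), Prex2 (−1.40), Hhip (−1.37), Lyz2 (−1.33) and Frem2 (−1.32). Car5b lies on X. The limit of 5000 bp applies to the mean of both libraries, so extreme ratios here and below can rest on few covered bp in the lower library. At Ccdc192 this was 1745 bp in wild type, and at Gm9507 2720 bp in the knockout.

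Of the knockout peaks at day 0, 54814 (24.7%, 24.5 to 24.8) overlapped no wild-type peak, and 31577 wild-type peaks (15.9%, 15.7 to 16.0) overlapped no knockout peak. The bases covered in both lists made up 0.607 of the bases covered in either. No test was run, with 1 library per group. With windows of 10 kb, the core pluripotency, formative, neural progenitor, endoderm and fibroblast medians were 0.07, −0.13, −0.02, 0.06 and 0.22, all inside the random range (percentiles 75.3, 2.55, 20.2, 71.4 and 96.2). The core pluripotency median lay inside it under 5 of 10 alternative settings, and the formative and neural progenitor medians also did so with numbers of peaks (percentiles 3.65 and 6.75). With the widest peaks in equal numbers, the balance of end peaks turned, to 500 genes with one in the knockout alone and 1048 in wild type alone. Peaks without overlap were then nearly equal (43678 and 43533), which largely follows from cutting both lists to the same length.

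Knockout and wild-type cells at day 5 of neural differentiation were compared to ask whether cells without the phosphatases leave the pluripotent state alike. Core pluripotency loci covered more bp in the knockout relative to the median locus, with Nanog at 0.25, Sall4 at 0.24, Dppa4 at 0.70 and Pou5f1 at 0.16. Neural progenitor loci covered less, including Pax6 (−0.42), the Notch effector Hes5 (−0.42) and the intermediate filament gene Nes (−0.31). The gene ends of Lin28a, an RNA-binding regulator of stem cells, and of Tcl1 had a peak in the knockout and none in wild type. At Ezh2, the catalytic subunit of Polycomb complex 2, the knockout value was 0.81.

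The core pluripotency list had a median of 0.17 (percentile 99.6) with 7 of 10 loci above the median locus, among them Sox2 at 0.08, while Utf1 stood at −0.03. Neural progenitor loci had a median of −0.27 (percentile 0.02), and 17 of 20 lay below the median locus, Sox1 at −0.24. At the Pax6 low-coordinate end, peaks covered 1266 bp of the window in wild type and 556 bp in the knockout. Bivalent developmental regulators, genes whose promoters carry both activating and Polycomb marks in stem cells, had a median of −0.10 (percentile 0.8) with 50 of 68 loci below the median locus. Polycomb and Trithorax genes had one of 0.19 (percentile 99.2), with Kdm6a, an X-linked histone demethylase gene, at 0.75. Among naive and formative genes, values were −0.10 for Klf4, −0.13 for Zfp42, −0.27 for Esrrb, −0.16 for Fgf5 and −0.06 for Otx2. Fibroblast marker loci had a median of −0.17 (percentile 4.5), and the wild-type library of this pair is the one with peaks at Y-linked genes.

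**Figure D1:**
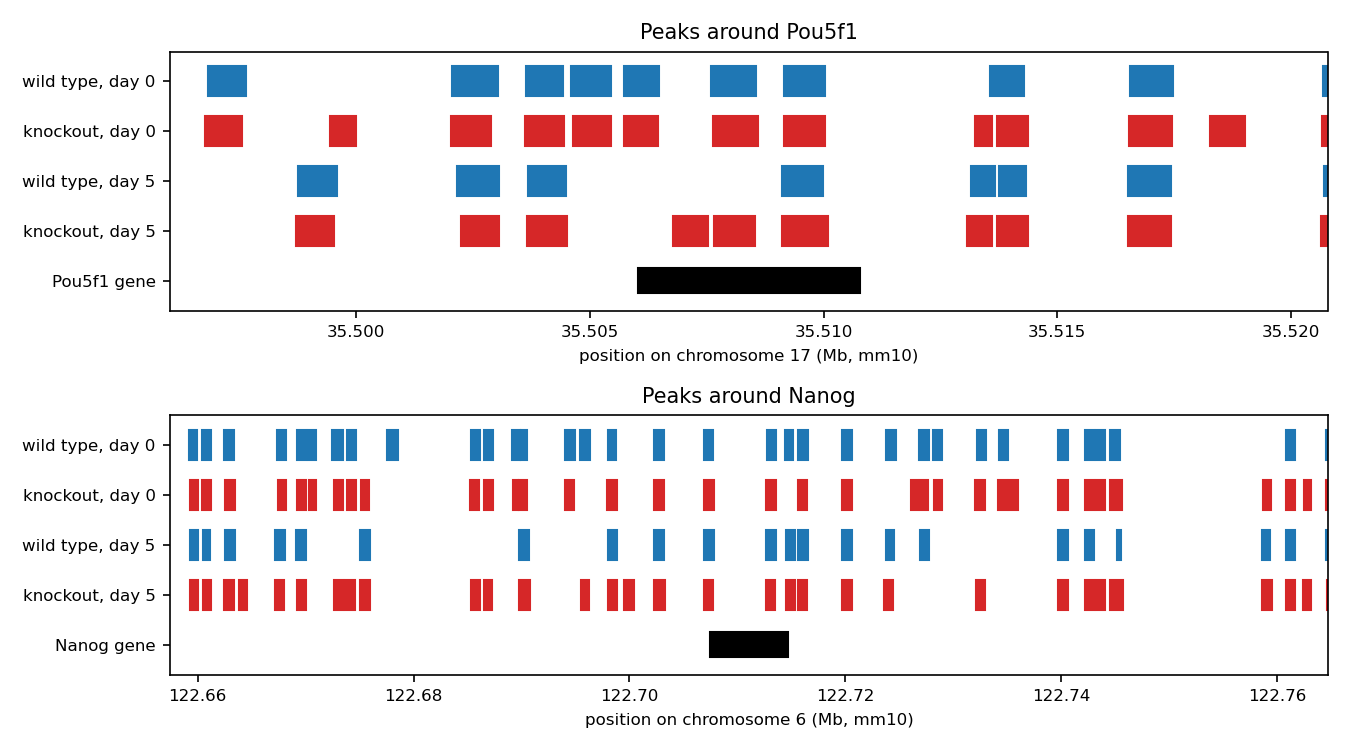
Peaks (bars) of the 4 libraries along the mm10 genome, with position in Mb on the horizontal axis, wild type in blue, the knockout in red and the gene in black. Both peaks between 35504596 and 35506481 on chromosome 17, just before and over the start of Pou5f1, appear in both day 0 libraries and in neither day 5 library.

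At Pou5f1 (chromosome 17, 35506032 to 35510777), the peak over the low-coordinate gene end spanned 35505728 to 35506481 in wild type and 35505723 to 35506455 in the knockout at day 0, and no peak overlapped that gene end at day 5 in either genotype. Within 1 kb of it, the knockout at day 5 had a peak from 35506776 to 35507526, inside the gene, and wild type had none. A peak inside the gene was listed at 35507585 to 35508560 in wild type at day 0 and at 35507660 to 35508534 in the knockout at day 5, and none was listed there in wild type at day 5. In the 100 kb around the Nanog end (gene on chromosome 6, 122707489 to 122714633), peaks covered 26.2 kb in wild type and 24.8 kb in the knockout at day 0, and 15.9 and 23.5 kb at day 5.

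At day 5, the other 16 lists had medians inside the central 95% of random lists. They were 0.05 for naive pluripotency, 0.01 for formative, −0.05 for neuron, −0.10 for glia, −0.03 for mesoderm, 0.03 for endoderm, 0.03 for trophoblast, −0.03 for epidermal and neural crest, −0.13 for blood and endothelium, 0.78 for 2-cell-like, −0.16 for germ line, −0.17 for fibroblast, −0.12 for Hox, 0.01 for imprinted, −0.07 for mitosis and −0.15 for housekeeping genes.

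Extreme members at day 5, among those with at least 2000 bp covered on average, ran from −0.12 (Lin28a) to 0.70 (Dppa4) in the core pluripotency list, from −0.27 (Esrrb) to 1.22 (Nr0b1) in the naive list and from −0.39 (Pou3f1) to 0.64 (Wnt8a) in the formative list. Nr0b1 lies on X, whose share of peaks was higher in the knockout. Progenitor genes of the neural lineage ran from −0.43 (Fabp7) to 0.45 (Sox21) and neuronal genes from −0.72 (Elavl4) to 0.30 (Neurog1), and the lowest glial gene was Olig1 (−0.66). Mesoderm genes ran from −0.51 (Hand2) to 0.50 (Mixl1), endoderm genes from −0.47 (Afp) to 0.44 (Hnf4a), epidermal and neural crest genes from −0.21 (Tfap2b) to 0.76 (Foxd3) and blood and endothelial genes from −0.71 (Runx1) to 0.86 (Hbb-bs). Values ran from −0.31 (Eomes) to 0.14 (Hand1) for trophoblast, from −0.66 (Mael) to 1.28 (Dazl) for germ line, from −0.14 (Duxf3) to 1.04 (Tcstv1) for 2-cell-like and from −1.28 (Postn) to 0.92 (Tagln) for fibroblast genes. They ran from −0.66 (Olig1) to 0.53 (Nkx2-1) for bivalent regulators, from −0.35 (Hoxb3) to 0.26 (Hoxd3) for Hox genes and from −0.33 (Igf2r) to 0.64 (Zim1) for imprinted genes. In the remaining lists they ran from −0.32 (Mad2l1) to 0.26 (Bub1b) (mitosis), from −0.18 (Pcgf6) to 0.81 (Ezh2) (Polycomb and Trithorax) and from −0.33 (Actb) to 0.17 (Polr2a) (housekeeping).

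An end peak was present in the day 5 knockout and absent in wild type at genes including Gata4, Gfap, Hnf4a, Hoxa7, Hoxd12, Lin28a, Nr2f2, Tcl1 and Tcstv1. Genes with one in wild type and none in the knockout included Gata3. Genome-wide, 995 genes had an end peak in the knockout alone and 374 in wild type alone. The highest locus ratios belonged to Cd8a (2.54), LOC115490200 (2.51), Rhox12 (2.08), Fthl17a (2.06) and Cul2 (1.93), and the lowest to Pde7b (−1.72), Nav3 (−1.71), Fbxl17 (−1.69), Spaca1 (−1.68) and A930009A15Rik (−1.64). Of these, Rhox12 and Fthl17a lie on X. The highest ratios rest on few covered bp in wild type: 894 for Cd8a, 903 for LOC115490200, 1828 for Rhox12, 1555 for Fthl17a and 1793 for Cul2. For the lowest, Pde7b had 3525 bp and Nav3 2651 bp in the knockout.

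In the knockout, 82078 peaks at day 5 (36.0%, 35.8 to 36.2) overlapped no wild-type peak. In wild type, 44051 (23.2%, 23.0 to 23.4) overlapped no knockout peak, and shared bases made up 0.484 of all covered bases. With windows of 10 kb, the core pluripotency, neural progenitor and Polycomb and Trithorax medians were 0.16, −0.10 and 0.30, inside the random range (percentiles 87.4, 6.35 and 96.2). Whole genes brought the core pluripotency and bivalent medians inside it (percentiles 97.3 and 3.76), and equal numbers of peaks the core pluripotency median (percentile 95.4). With the widest peaks in equal numbers, the balance of end peaks turned here as well, to 838 genes in the knockout alone and 1496 in wild type alone.

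Wild-type cells at day 5 and day 0 were compared to describe the wild-type course of neural differentiation. The day 5 library had end peaks at the Y-linked genes Eif2s3y, Uty and Ddx3y, and the day 0 library had none. A difference in cell source therefore cannot be separated from time for any list in this comparison. Loci of bivalent developmental regulators covered more bp at day 5 than the median locus, led by the endoderm and floor plate regulator Foxa2 (0.78). Neural progenitor loci did so as well, including Irx3 (0.60), Zic1 (0.45) and Sox1 (0.30), and the gene end of Dcx, a microtubule protein of young neurons, had a peak at day 5 and none at day 0 (locus ratio 1.08). Among pluripotency genes, Nanog stood at −0.47, Sall4 at −0.42, Pou5f1 at −0.21 and Klf4 at 0.49, and neither pluripotency list lay outside the random range. The widest departure of any list was that of the fibroblast markers, including Dcn (1.77), Lum (1.70) and Postn (1.42), in the library that also had peaks at Y-linked genes. These ratios rest on few covered bp: 916 at day 0 and 3628 at day 5 for Dcn, 1302 and 4491 for Lum, and 2865 and 7182 for Postn. Dcn and Lum are neighbours whose windows overlap in part.

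The bivalent list had a median of 0.23 (0.08 at the lowest of 10 alternative settings), above all 10000 random lists (percentile 100), and 57 of 68 loci lay above the median locus. End peaks were listed at 66 of the 68 genes at day 0 and 67 at day 5, so most of these gene ends were already accessible in stem cells. Neural progenitor loci had a median of 0.20 (percentile 99.1) with 17 of 20 above the median locus, Nes at 0.28 and Pax6 at 0.06. Endoderm loci had one of 0.30 (percentile 98.8). Core pluripotency loci had a median of −0.21 at percentile 4.04, inside the random range, although 8 of 10 lay below the median locus, with Sox2 at 0.07 and Utf1 at 0.21. Naive and formative genes went both ways, with Klf4 at 0.49, Zfp42 at −0.51, Esrrb at 0.03, Fgf5 at 0.74 and Otx2 at −0.29. Polycomb and Trithorax genes had a median of −0.25 (percentile 1.17), with Ezh2 at −1.18.

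Fibroblast marker loci had a median of 0.48 (percentile 99.99), which was 0.17 at the lowest of 10 alternative settings, and 12 of 16 lay above the median locus. The collagen genes Col1a1, Col1a2 and Col3a1 had ratios of 0.15, 0.54 and 1.24, while Tagln of smooth muscle and fibroblasts stood at −1.13. Hox genes had a list median of 0.15, with windows shared between neighbours. By cluster, day 5 against day 0 ratios in wild type were 0.16 at Hoxa, 0.19 at Hoxb, 0.12 at Hoxc and −0.16 at Hoxd.

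In wild type over time, the other 14 lists had medians inside the random range. They were −0.21 for core pluripotency, −0.02 for naive pluripotency, −0.07 for formative, 0.18 for neuron, 0.16 for glia, −0.01 for mesoderm, 0.16 for trophoblast, 0.11 for epidermal and neural crest, 0.01 for blood and endothelium, −0.27 for 2-cell-like, 0.00 for germ line, 0.12 for imprinted, −0.02 for mitosis and 0.00 for housekeeping genes.

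From day 0 to day 5 in wild type, ratios of members with at least 2000 bp covered on average ran from −0.47 (Nanog) to 0.21 (Utf1) for core pluripotency, from −0.53 (Nr0b1) to 0.49 (Klf4) for naive and from −0.53 (Wnt8a) to 0.74 (Fgf5) for formative genes. Neural lists ran from −0.30 (Sox3) to 0.60 (Irx3) (progenitor), from −0.32 (Rbfox3) to 1.08 (Dcx) (neuron) and from −0.47 (Gfap) to 0.93 (Slc1a2) (glia). The highest endoderm gene was Afp (0.99), and the lists of mesoderm, epidermis with neural crest, and blood with endothelium ran from −0.92 (Mixl1) to 0.60 (Kdr), from −0.54 (Krt14) to 0.49 (Trp63) and from −0.57 (Hbb-bs) to 1.31 (Ptprc). Trophoblast, germ line and 2-cell-like genes ran from −0.13 (Elf5) to 0.39 (Esx1), from −0.55 (Hormad1) to 0.81 (Slc25a31) and from −1.09 (Zfp352) to −0.06 (Duxf3). Fibroblast, bivalent, Hox and imprinted genes ran from −1.13 (Tagln) to 1.77 (Dcn), from −0.45 (Msx1) to 0.78 (Foxa2), from −0.18 (Hoxc4) to 0.32 (Hoxb9) and from −0.48 (Nnat) to 0.64 (Plagl1). Mitotic, Polycomb and Trithorax, and housekeeping genes ran from −0.37 (Wee1) to 0.73 (Mad2l1), from −1.18 (Ezh2) to 0.19 (Pcgf6) and from −0.28 (Polr2a) to 0.25 (Rplp0).

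Genes with an end peak in wild type at day 5 and not at day 0 included Col3a1, Hoxb5, Lhx1, Lum and Trp63. Those with one at day 0 and not at day 5 included Dnmt3a, Gfap, Pou5f1, Prdm14 and Tcl1. In all, 586 genes had an end peak at day 5 alone and 857 at day 0 alone. Genome-wide, the highest ratios were those of Ccser1 (2.48), Tspan18 (2.44), Pde7b (2.40), Ppp1r17 (2.23) and 4930583I09Rik (2.21), and the lowest those of Vmn2r2 (−2.07), Zfp936 (−1.93), Bud31 (−1.47), Gm52051 (−1.47) and Adam17 (−1.47). Peaks covered only 1633 bp around Ccser1 and 1901 bp around Pde7b at day 0, and 1776 bp around Vmn2r2 at day 5.

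Of the wild-type peaks, 62645 at day 5 (33.0%, 32.8 to 33.3) overlapped no day 0 peak, and 71687 at day 0 (36.0%, 35.8 to 36.3) overlapped no day 5 peak, with shared bases making up 0.436 of all covered bases. Against random lists matched on gene density as well, the neural progenitor and endoderm medians lay inside the range, at percentiles 96.8 and 96.2, and with windows of 10 kb at 91.9 and 84.0 (medians 0.07 and 0.07). Those windows also brought the Hox (0.07, percentile 97.1) and Polycomb and Trithorax (−0.34, percentile 3.16) medians inside. The day 5 library of this comparison is the one with peaks at Y-linked genes.

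**Figure D2:**
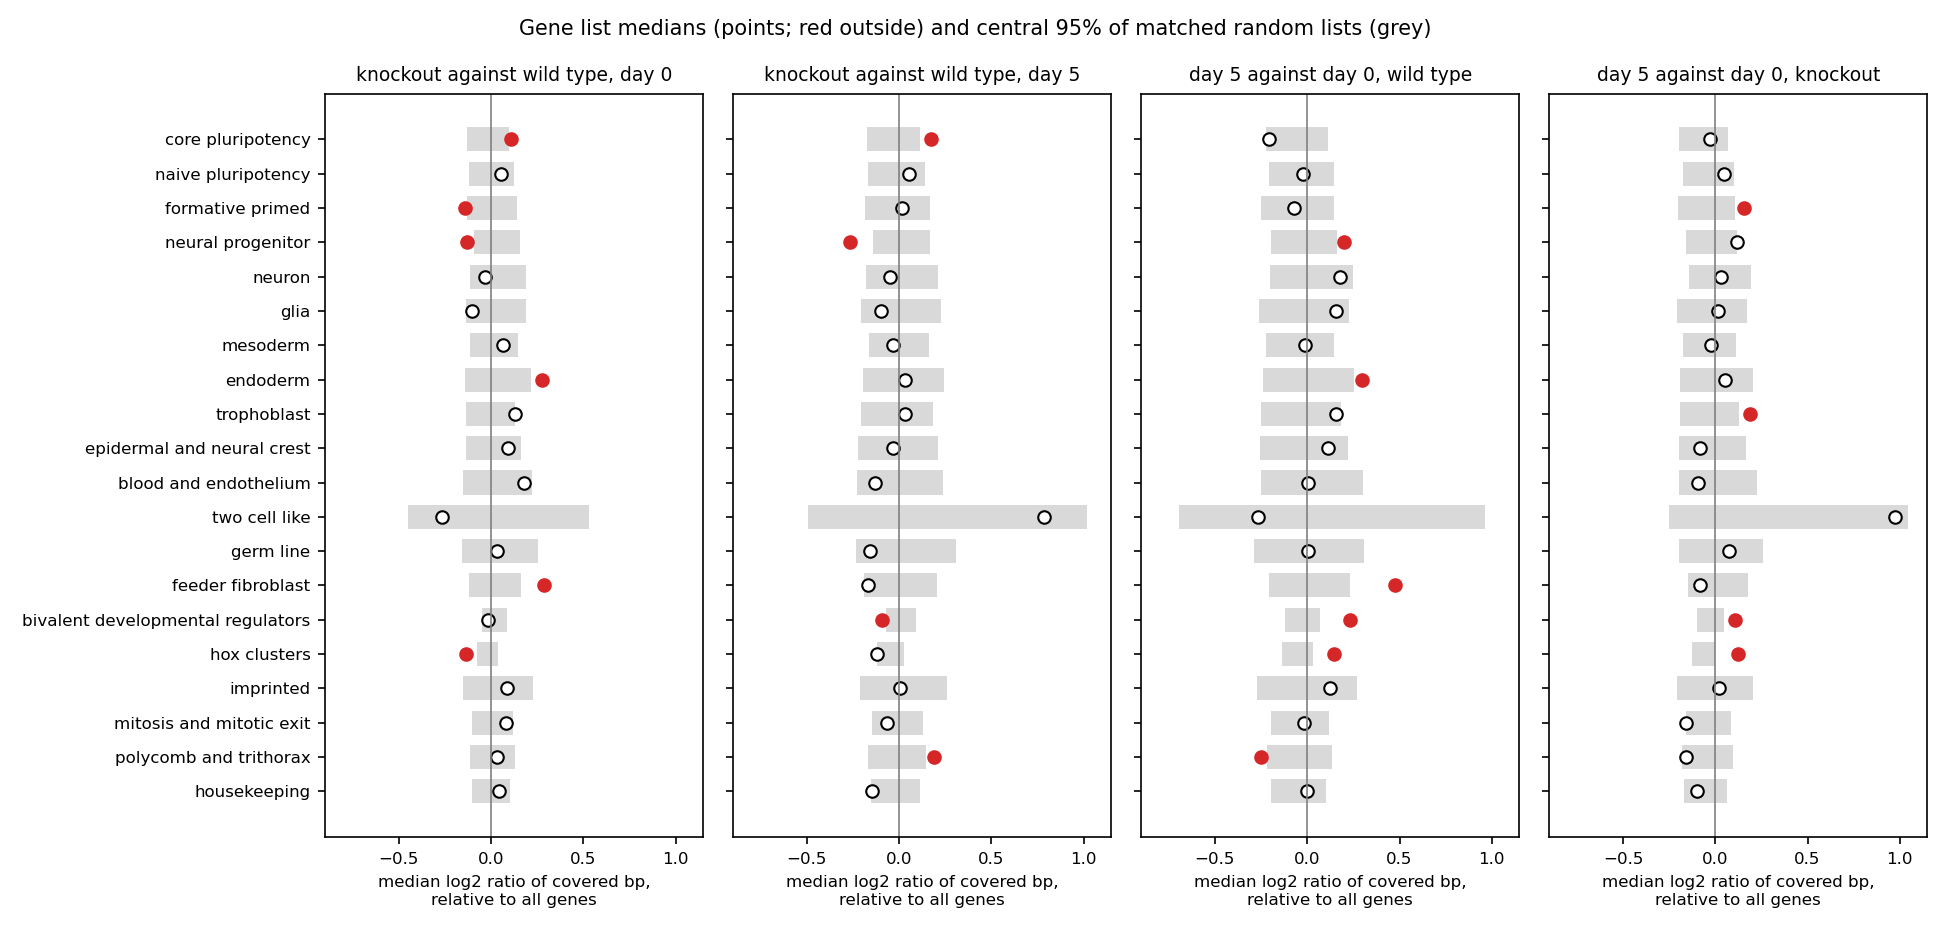
Median log2 ratio of covered bp of 20 gene lists (points), relative to all genes, in the 4 comparisons of 1 library with 1 library. Grey bars span the central 95% of 10000 random lists matched on covered bp, and red points lie outside them. The fibroblast markers reach 0.48 in wild type over time and −0.08 in the knockout.

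Knockout cells at day 5 and day 0 were compared in the same way. Bivalent regulator loci covered more bp at day 5 than the median locus, led by the endoderm regulator Sox17 (1.05). The neuronal list had a median of 0.03 (percentile 53.0), inside the random range, although Dcx stood at 1.11 and had an end peak at day 5 and none at day 0. Core pluripotency loci stayed near the median locus, with Nanog at −0.04, Pou5f1 at −0.02 and Sox2 at −0.04. Formative and trophoblast loci covered more, including Wnt8a (0.33) and Elf5 (0.56).

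In the knockout, bivalent regulators had a median of 0.11 (percentile 99.99), with 41 of 68 loci above the median locus. Formative genes had one of 0.15 (percentile 99.5), 8 of 10 above, with Fgf5 at 0.24 and Otx2 at −0.26. Trophoblast genes had one of 0.19 (percentile 99.5). The core pluripotency median was −0.03 (percentile 70.9), with 8 of 10 loci below the median locus by small amounts and Utf1 at 0.04. Neural progenitor loci had a median of 0.12 at percentile 97.45, just inside the random range and outside it under 5 of 10 alternative settings, with Sox1 at 0.15, Pax6 at −0.02 and Nes at −0.10. Among those settings, at most 1 member per 100 kb left the list and its median unchanged, and only the random lists differed (percentile 97.54). Among naive genes, Klf4 stood at −0.21, Zfp42 at −0.17 and Esrrb at −0.31. The Hox list had a median of 0.12, and the cluster ratios were 0.32 at Hoxa, 0.13 at Hoxb, −0.07 at Hoxc and 0.20 at Hoxd.

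Over time in the knockout, the other 16 lists lay inside the random range. They were −0.03 for core pluripotency, 0.05 for naive pluripotency, 0.12 for neural progenitor, 0.03 for neuron, 0.01 for glia, −0.02 for mesoderm, 0.05 for endoderm, −0.08 for epidermal and neural crest, −0.09 for blood and endothelium, 0.97 for 2-cell-like, 0.07 for germ line, −0.08 for fibroblast, 0.02 for imprinted, −0.16 for mitosis, −0.16 for Polycomb and Trithorax and −0.10 for housekeeping genes.

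Again among members with at least 2000 bp covered on average, the pluripotency lists ran from −0.23 (Lin28a) to 0.04 (Utf1) (core), from −0.51 (Klf5) to 0.15 (Dppa3) (naive) and from −0.26 (Otx2) to 0.33 (Wnt8a) (formative) over time in the knockout. Those of the neural lists ran from −0.66 (Sox3) to 0.53 (Meis2) (progenitor), from −0.36 (Rbfox3) to 1.20 (Syt1) (neuron) and from −0.32 (Olig2) to 1.16 (Aqp4) (glia). Germ layer lists ran from −0.44 (Tbx6) to 0.29 (Nkx2-5) (mesoderm), from −0.16 (Dab2) to 1.05 (Sox17) (endoderm), from −0.60 (Krt14) to 0.82 (Trp63) (epidermis and neural crest) and from −1.10 (Runx1) to 0.78 (Ptprc) (blood and endothelium). Further lists ran from −0.26 (Eomes) to 0.56 (Elf5) (trophoblast), from −0.63 (Mael) to 0.84 (Dazl) (germ line), from −1.02 (Zfp352) to 1.02 (Tcstv1) (2-cell-like) and from −0.73 (Postn) to 0.52 (Lum) (fibroblast). Regulator lists ran from −0.53 (Irx1) to 1.05 (Sox17) (bivalent), from −0.15 (Hoxc11) to 0.35 (Hoxa5) (Hox) and from −0.40 (Nnat) to 0.43 (Igf2) (imprinted). The last lists ran from −0.56 (Ccnb1) to 0.32 (Mad2l1) (mitosis), from −0.45 (Dpy30) to 0.28 (Kdm6a) (Polycomb and Trithorax) and from −0.41 (Pgk1) to 0.24 (Tubb5) (housekeeping).

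The knockout had an end peak at day 5 and none at day 0 at genes including Dcx, Gata4, Hoxa11, Lum, Neurog2, T and Tcstv1. It had one at day 0 and none at day 5 at genes including Gata3, Rbfox3 and Runx1. These were among 653 genes with an end peak at day 5 alone and 533 at day 0 alone. The highest locus ratios were those of Akain1 (2.06), Krtap27-1 (2.06), Frem2 (1.78), Amph (1.70) and Gm9507 (1.65), and the lowest those of Ell2 (−1.54), Trps1 (−1.17), Runx1 (−1.10), Fancf (−1.09) and D3Ertd751e (−1.04).

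Of the knockout peaks, 62387 at day 5 (27.4%, 27.2 to 27.6) overlapped no day 0 peak and 56538 at day 0 (25.4%, 25.3 to 25.6) overlapped no day 5 peak, with shared bases making up 0.521 of all covered bases. The formative median was inside the random range with equal numbers of peaks (percentile 82.9), and the bivalent, formative and trophoblast medians were inside it with windows of 10 kb (percentiles 85.0, 96.9 and 93.4). On autosomes the trophoblast median (percentile 95.3) and with numbers of peaks the bivalent median (percentile 94.1) also lay inside. With the widest peaks in equal numbers, the balance of end peaks turned, to 883 genes at day 5 alone and 1055 at day 0 alone.

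The course of both genotypes was then set side by side over regions joined across the 4 libraries. Of 164833 regions with a peak in both day 0 libraries, 29369 (17.8%, 17.6 to 18.0) had none at day 5 in wild type alone, 5603 (3.40%, 3.31 to 3.49) had none in the knockout alone, and 18815 (11.4%, 11.3 to 11.6) had none in either genotype. Thus 61.0% (60.5 to 61.4) of the shared day 0 regions that were absent in wild type at day 5 were still listed in the knockout. Conversely, 22.9% (22.4 to 23.5) of those absent in the knockout were still listed in wild type. Regions new at day 5 were listed in wild type alone (30090), in the knockout alone (32999) or in both (16475). Gene ends lay within 1 kb of 6.05% of the regions absent in wild type alone, of 8.14% of those absent in the knockout alone and of 16.8% of those in all 4 libraries. With the widest peaks in equal numbers, 22031 regions were absent in wild type alone and 10852 in the knockout alone, and the shares still listed in the other genotype were 55.4 and 38.0%. The counts rest on the wild-type day 5 library, which had the shortest list and the peaks at Y-linked genes. Regions absent in wild type alone can therefore reflect list length or cell source as well as genotype, which was not tested.

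**Figure D3:**
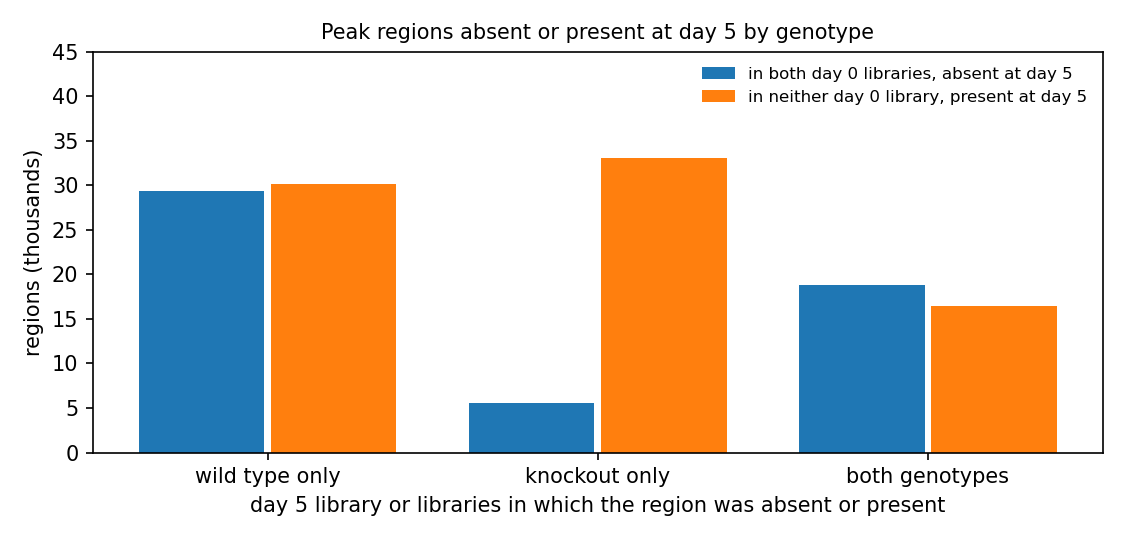
Number of regions (axis in units of 1000) that were absent at day 5 although both day 0 libraries had them (blue), or present at day 5 although neither day 0 library had them (orange), in wild type alone, the knockout alone or both genotypes. Bars are counts from 1 library per group, and the blue bars stand at 29369, 5603 and 18815 regions.

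The difference between the genotypes in the day 5 against day 0 ratio was lowest for the fibroblast markers, with a median of −0.53 (percentile 0.01). Bivalent regulators had a difference of −0.11 (percentile 1.78), housekeeping genes of −0.18 (percentile 1.93) and Polycomb and Trithorax genes of 0.24 (percentile 99.4). The core pluripotency difference was 0.12 (percentile 91.8) and the neural progenitor difference −0.09 (percentile 19.2), both inside the random range, so the courses of these lists were not told apart. The other lists lay inside it as well, at 0.03 for naive pluripotency, 0.15 for formative, −0.11 for neuron, −0.05 for glia, 0.00 for mesoderm, −0.10 for endoderm, −0.07 for trophoblast, 0.03 for epidermal and neural crest, −0.25 for blood and endothelium, 0.73 for 2-cell-like, 0.02 for germ line, 0.05 for Hox, −0.10 for imprinted and −0.10 for mitosis genes. Over the 20 lists and the 5 contrasts, 24 of 100 medians lay outside the central 95%, where 5 would on average for genes drawn at random. Some lists share members, neighbouring members such as Hox genes share windows, and the contrasts share libraries. The 24 medians are therefore not independent, and their excess over 5 was not tested. With windows of 10 kb, the fibroblast difference was −0.25 (percentile 2.91) and the Polycomb and Trithorax difference 0.31 (percentile 96.3), both inside the random range, and the housekeeping difference turned to 0.14. Whole genes brought the Polycomb and Trithorax (percentile 95.2) and bivalent (percentile 8.41) differences inside. The bivalent difference also came inside with numbers of peaks (percentile 2.5) and with gene density matched (percentile 4.61), and the housekeeping difference with equal numbers of peaks (percentile 7.97).

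The widest regions listed in a single library lay inside genes or at a distance from them. In wild type at day 0 they were in Pwwp2a (chromosome 11, 43700255 to 43701593), in Dock10 (chromosome 1, 80741118 to 80742391) and on chromosome 4 (40571218 to 40572509). The knockout at day 0 had them in Ccnl1 (chromosome 3, 65949545 to 65951574) and on chromosomes 13 (96975669 to 96977682) and 7 (132172009 to 132173909). Wild type at day 5 had them in Slit2 (chromosome 5, 48060555 to 48062250), in Tnrc18 (chromosome 5, 142730951 to 142732593) and on chromosome 8 (7206143 to 7207711). In the knockout at day 5 they lay in Pak6 (chromosome 2, 118686072 to 118687833) and on chromosome 3, at 152034002 to 152035906 and 78999709 to 79001467.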

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

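The tests that weigh explanations in this part were chosen after the results were seen, although the settings with equal numbers of peaks, numbers of peaks, whole genes and windows of 10 kb were fixed earlier. Fibroblast marker loci had medians of opposite sign over time, 0.48 (log2) in wild type and −0.08 in the knockout, a difference of −0.53, and the knockout median lay inside the random range (percentile 12.1). Housekeeping loci had a knockout against wild type median of 0.04 at day 0 and −0.15 at day 5, and a difference of −0.18 between the genotypes over time, which turned to 0.14 with windows of 10 kb and lay inside the random range with equal numbers of peaks (percentile 7.97). With 1 library per group, neither difference was tested.

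Fibroblast marker loci were higher in wild type at day 5 than at day 0. Against random lists matched on covered bp and gene density, their median kept percentile 99.98, which argues against a trend with either property as the whole cause. The wild-type day 0 library may have been low at these loci, since the knockout exceeded it there (median 0.29, percentile 99.91). Cells of another origin in the wild-type day 5 library, such as feeder cells that escaped removal, could also contribute and stay open: 3 Y-linked genes had end peaks there and in no other library, but the knockout against wild type median at day 5 was −0.17 (percentile 4.5), inside the random range, though below it with whole genes, numbers of peaks and equal numbers of peaks (percentiles 1.53, 2.2 and 1.24). The sex of the feeder cells is not given in the sources used here, another stem cell line in that culture would give the same Y-linked peaks, and no biological explanation of the marker loci was tested.

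Neural progenitor loci were lower in the knockout at day 5, and core pluripotency loci higher. For the neural loci, the percentile was 0.14 with gene density matched. This argues against the longer knockout list, acting through covered bp and gene density, as the whole cause. With equal numbers of peaks the percentile was 0. That setting also turned the balance of end peaks at day 5 (838 genes in the knockout alone, 1496 in wild type alone). It thus removed end peaks mainly from the knockout and cannot decide about list length. The day 0 pair, which shares no library with the day 5 pair, gave percentile 0.28 (0.48 with density matched). This argues against a single atypical day 5 library as the whole cause. The median was −0.13 at day 0 and −0.27 at day 5, so such a library may still have contributed to the day 5 value. With windows of 10 kb, however, the neural median lay inside the random range at both days (percentile 20.2 at day 0 and 6.35 at day 5), and at day 0 also with numbers of peaks (percentile 6.75), so these readings depend on the setting. For the core pluripotency loci these explanations stay open: the percentile was 98.8 with gene density matched but 95.4 with equal numbers of peaks, and at day 0 it was 98.4, or 96.9 with density matched. Cells of another origin in the wild-type day 5 library could also lower pluripotency loci there, which was not tested, and with genotype and cell line inseparable an effect of the knockout on neural loci remains a hypothesis.

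The X chromosome had a higher share of peaks in the knockout at both days. In bins of 10 Mb the median log2 ratio was 0.24 at day 0 and 0.42 at day 5. This was above the central 95% of 64 autosomal bins with no more peaks than the richest X bin (upper bounds 0.20 and 0.23). The values argue against a longer list acting alike on all peak-poor regions. The autosomal bins were matched by that limit only and peaks carried no height, so a longer list that adds weaker X peaks stays open. All 16 X bins (100%) lay above the autosomal median at day 0, and likewise 100% at day 5, which is consistent with a chromosome-wide difference such as X copy number or X activity. Over time, all 16 X bins also lay above the autosomal median in the knockout (median 0.22), and 7 did in wild type (median −0.04). The knockout median over time lay inside the central 95% of those 64 autosomal bins (upper bound 0.32). The count of X bins alone thus does not tell a lasting difference between the lines from a change over time. Whether X copy number or X activity applies, and whether it belongs to the genotype or to the cell line, was not tested.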

How the results depend on the processing

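The tests with a peak at either gene end, with gene density matched and with 1 list member per 100 kb were chosen after the data were seen. Of the counts of peaks, gene ends, joined regions and lists, 116 values stayed within 1.5 times the reported count and 10 moved further. With the widest peaks in equal numbers, genes with an end peak in wild type and not in the knockout numbered 1048 at day 0 (converse 500) and 1496 at day 5 (converse 838), and genes with one in the knockout at day 0 and not at day 5 numbered 1055 (converse 883), so the balance turned in all of these. Regions absent at day 5 in the knockout alone numbered 10852, and of regions absent in 1 genotype the other kept 55.4% (absent in wild type) and 38.0% (absent in the knockout). This setting changes both the number of peaks and which peaks are kept. Lists outside the random range numbered 3 (genotypes at day 0), 2 (wild type over time), 2 (knockout over time) and 2 (difference between genotypes) with windows of 10 kb, 2 (difference) with whole genes and 7 (genotypes at day 5) with gene density matched.

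Of 24 list medians outside the random range, 4 stayed outside under all 10 alternatives: fibroblast markers and bivalent regulators in wild type over time, and Hox genes at day 0 and in the knockout over time. The smallest values of these medians were 0.17, 0.080, −0.052 and 0.045, against 0.48, 0.23, −0.14 and 0.12 as reported. Over all lists and settings, 933 medians kept their place, 36 moved inside the range and 28 moved outside it. A further 3 turned direction and are counted apart, although they also crossed the edge of the range. Windows of 10 kb moved the most: 17 medians came inside, namely at day 0 core pluripotency (0.073), formative (−0.13), neural progenitor (−0.016), endoderm (0.060) and fibroblast (0.22), at day 5 core pluripotency (0.16), neural progenitor (−0.10) and Polycomb and Trithorax (0.30), in wild type over time neural progenitor (0.071), endoderm (0.067), Hox (0.068) and Polycomb and Trithorax (−0.34), in the knockout over time formative (0.14), trophoblast (0.10) and bivalent (0.0024), and for the difference fibroblast (−0.25) and Polycomb and Trithorax (0.31). The 3 medians that turned direction did so with these windows. Trophoblast at day 5 (−0.17, percentile 2.21) and the germ line difference (−0.48, percentile 2.08) thereby moved outside the range, and the housekeeping difference (0.14, percentile 78.0) came inside. Without a turn, windows of 10 kb moved outside blood and endothelium (0.29) and germ line (0.47) at day 0, glia (−0.26) and mesoderm (−0.16) at day 5 and endoderm in the knockout over time (0.19).

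Whole genes brought inside core pluripotency at day 0 (0.072) and day 5 (0.14), bivalent at day 5 (−0.077), and Polycomb and Trithorax (0.14) and bivalent (−0.075) for the difference. They moved outside fibroblast (−0.19) and Hox (−0.12) at day 5, neuron in wild type (0.22) and neural progenitor in the knockout (0.16). Numbers of peaks brought inside formative (−0.11) and neural progenitor (−0.080) at day 0, bivalent in the knockout (0.00) and bivalent for the difference (−0.10), and moved outside trophoblast at day 0 (0.17), fibroblast (−0.21) and Hox (−0.17) at day 5 and neural progenitor in the knockout (0.10). Equal numbers of peaks brought inside core pluripotency at day 0 (0.064) and day 5 (0.10), formative in the knockout (0.025) and housekeeping for the difference (−0.14). They moved outside bivalent at day 0 (−0.089), fibroblast (−0.20) and Hox (−0.24) at day 5, core pluripotency (−0.25) and trophoblast (0.20) in wild type and 2-cell-like genes in the knockout (1.11). Matching gene density left the medians as reported and brought inside core pluripotency at day 0 (0.11), neural progenitor (0.20) and endoderm (0.30) in wild type and bivalent for the difference (−0.11), and put outside Hox (−0.12), 2-cell-like (0.78) and housekeeping (−0.15) genes at day 5 and 2-cell-like genes in the knockout (0.97). On autosomes, trophoblast in the knockout came inside (0.13), and blood and endothelium at day 0 (0.26) and neural progenitor in the knockout (0.16) moved outside. The latter also did so with a mean of at least 2000 bp (0.13) and with 1 member per 100 kb (0.12). With 1 member per 100 kb that list kept all 20 members and its median, so only the random lists differed (percentile 97.54 against 97.45). The same setting brought core pluripotency at day 0 inside (0.082), and a pseudocount of 2000 bp moved 2-cell-like genes in the knockout outside (0.61).

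The cause was not tested. Each group held 1 library and no replicate block was fitted. A fit of genotype and day together, which would leave 1 residual degree of freedom, was not run. The motif alternatives and the test with the outermost 5' end were not run. Depth is unknown, so peak loss by fewer reads limits every count.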

Other observations

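The tests behind the X and Y values in this part were chosen after the results were seen. Genes of the X-inactivation centre held peaks in every library: 5, 5, 4 and 5 within Xist and 16, 16, 13 and 17 within Tsix (wild type and knockout at day 0, then wild type and knockout at day 5). On Y, 16 peaks in each of wild type at day 0, the knockout at day 0 and wild type at day 5 and 13 in the knockout at day 5 lay beyond 90 Mb, and the only others were 4 in wild type at day 5 and 1 in the knockout at day 5 (4156881 to 4157580).

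Genes of the 2-cell-like state, a rare state of stem cell cultures, had few peaks. Tcstv1 had an end peak in the knockout at day 5 (860 bp of the window) and in no other library, and around Zscan4d peaks covered 1757, 909, 0 and 2984 bp in the same order of libraries. The list median over time in the knockout was 0.97 (percentile 96.5), inside the random range, and copies of these genes can share reads.

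Chromosomes 2, 8, 10, 11, 12 and 17 had a lower share of peaks in the knockout at both days, with log2 ratios of −0.03, −0.14, −0.09, −0.09, −0.10 and −0.11 at day 0 and −0.11, −0.06, −0.11, −0.11, −0.13 and −0.03 at day 5. Regions with a peak in both knockout libraries and no wild-type library numbered 12103, and the converse 2806, with the knockout lists longer at both days.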
